A study of Mus musculus with 6 samples.

How the data were processed

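RNA-seq was performed on total RNA from mouse embryonic fibroblasts that expressed E1A and HRasV12, in 3 libraries with a control hairpin (shLuc_dox) and 3 with a hairpin against Mettl3 (shMettl3_dox). All 6 were treated with 0.2 ug/ml doxorubicin for 6 hours, per the labels. The submitters' processing notes name fastp, STAR, featureCounts 1.5.3, DESeq2 and the build mm10, without roles or parameters; whether counting used strand is not given in the sources used here.

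The deposited whole-series table gives FPKM (reads scaled by the authors to gene length and to library size) for 54532 genes, of which 26328 were above 0 in at least 1 library. The second deposited table holds 1960 genes that the authors listed as lower in shMettl3_dox, with a normalized read count signal per library, made by the authors by dividing reads by 1 size factor per library. That table also holds the authors' log2 fold changes and the authors' p-values with adjusted p-values, without naming the test in its header. Its shMettl3 column names carry the number 2 after shMettl3, and no other hairpin against Mettl3 is labelled. All listed genes had an adjusted p under 0.05 in the authors' deposited table and a log2 fold change of -0.0989 or lower. No column belonged to other samples.

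Whole reads were recovered from both tables. The normalized read counts were whole multiples of 1 step per library for 100% of values. FPKM multiplied by a library factor and the GENCODE M21 union exon length gave whole reads, within 0.001 of a read, for 96.7% of the genes above 0. Another whole-number length did so for the remaining 872 genes. From FPKM alone, the reads of these 872 are known only up to a common multiple. In 278 of them the length was taken as a multiple of the smallest that served. This leaves ratios between libraries as they are, but not the read level that the count tests use. Recovered depth was 18188379, 20132543 and 17001642 reads in shLuc_dox replicates 1 to 3 and 25464040, 17652953 and 20402779 in shMettl3_dox replicates 1 to 3. For 98.5% of the listed genes the recovered reads equalled those behind the normalized counts; for the others the latter were used.

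Of the symbols deposited with FPKM, 25 were dates, 791 were empty and 1617 differed from GENCODE M21. Gene identifiers were used throughout, the M21 symbol replaced empty and date symbols, and list members were matched by the deposited symbol first and by the M21 symbol next. Coordinates are from GENCODE M21 (GRCm38, the assembly of mm10), 1-based.

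The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with eBayes and an intensity trend, for the 12098 genes with a mean of at least 1 FPKM over the 6 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of low genes. Log2 changes are on this scale unless a count test, another pseudocount or the authors are named. A count test is not the main test because the deposited unit is FPKM; edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads are alternatives. The 21 gene lists, with a union of the p53 target lists, were tested with limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 18 lists of at least 5 measured members. Calculations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.

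Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named Mettl3; Cdkn1a, Mdm2, Ccng1, Bax, Bbc3, Pmaip1, Trp53 and Mettl14; up to 4 measured members of each list with the smallest unadjusted p; the 10 protein-coding genes with the largest fall and the 10 with the largest rise among those that passed and whose groups did not overlap; and the 5 genes with the smallest adjusted p in the authors' deposited table. Predicted models were counted but not named. Some genes that the rule named are not reported here. Other list members are printed to make a group's count readable, chosen after their values were seen.

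Alternatives were other pseudocounts, filters and scalings, eBayes without the trend, array weights, the replicate number as a block, a minimum fold, count tests, other list tests and leaving out each library in turn. Removing a loess trend on GC content and length, and testing protein-coding genes alone, were added after seeing the data. On simulated counts drawn for the 12098 genes of this comparison, 50 genes were changed at each fold. Of these, limma recovered 14% at 1.2-fold, 72% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 9 false calls. On the same counts edgeR recovered 40%, 86%, 96% and 100%, with 10 false calls.

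The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.52 to 4.84 among shLuc_dox libraries, 4.00 between shMettl3_dox replicates 1 and 2, and 12.9 and 14.7 between these and replicate 3, which stood apart. An exon of 34 of the 105 named genes overlaps an exon of another gene, 26 of them on the opposite strand only; for Mettl3 the partner is Tox4, for Pltp it is Ctsa, for Junb it is Prdx2, for Cdc25b it is Spef1 and for Cxcl10 it is Art3. Reads in such overlaps cannot be assigned with certainty.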

Results

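The series compared Mettl3 knockdown with a control hairpin under DNA damage, and the authors deposited a list of the lower genes. Mettl3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA. The cells were mouse embryonic fibroblasts carrying the adenoviral oncoprotein E1A and an activated Hras, and doxorubicin is a topoisomerase II poison that causes DNA double-strand breaks. The 3 control libraries (shLuc_dox) held 17001642 to 20132543 recovered reads. The 3 knockdown libraries (shMettl3_dox) held 17652953 to 25464040. All 6 libraries came from doxorubicin-treated cells and no library without the drug was analysed here, so the comparison covers the treated state alone.

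Mettl3 itself (ENSMUSG00000022160, mm10 chromosome 14, 52294841 to 52305128, minus strand) was measured at 2.47, 3.14 and 2.59 FPKM in the shLuc_dox libraries and at 1.29, 1.53 and 1.65 FPKM in the shMettl3_dox libraries. Its mean fell from 2.73 ± 0.360 to 1.49 ± 0.185 FPKM (SD, n = 3 each), a ratio of 0.545. The change in log2(FPKM + 1) was -0.58 with a standard error of 0.108 (limma adjusted p = 0.00861), which the pseudocount makes smaller at this level; DESeq2 on recovered reads gave -0.90. These values rest on 136 to 321 recovered reads per library.

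Of 12098 genes tested, 1633 were lower and 1763 higher in shMettl3_dox, and 8702 did not pass. Large changes were mostly falls: 100 genes were lower and 22 higher by at least 2-fold on the log2(FPKM + 1) scale. The groups did not overlap in 45.1% of tested genes, where chance gives 10% for 3 against 3. With each library scaled by its protein-coding sum, which also makes the pseudocount smaller relative to the values, the split was 1914 lower and 1269 higher. The count of higher genes fell to 1059, 1013 and 1146 without shLuc_dox replicates 1, 2 and 3 and to 1060 without shMettl3_dox replicate 1, and the count of lower genes to 1060 without shLuc_dox replicate 2.

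**Figure D1:**
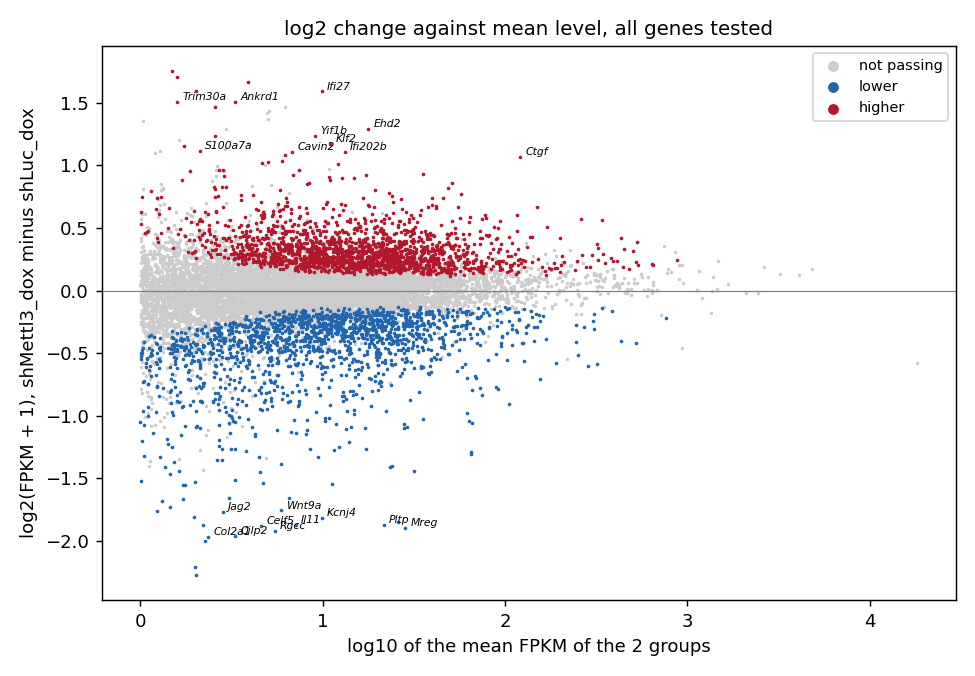
Each point is 1 of the 12098 genes tested; the horizontal axis is the log10 of the mean FPKM of the 2 groups and the vertical axis the difference in log2(FPKM + 1), shMettl3_dox minus shLuc_dox. Of the 1633 lower genes (blue) 100 lie at least 2-fold from 0, against 22 of the 1763 higher genes (red), and labels mark the named protein-coding genes with the largest changes.

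Among named protein-coding genes Col2a1 had the largest fall. Col2a1 (ENSMUSG00000022483, mm10 chromosome 15, 97975602 to 98004695, minus strand) encodes the chain of type II collagen. It went from 4.33 ± 0.129 to 0.363 ± 0.0318 FPKM, a ratio of 0.0838. The change in log2(FPKM + 1) was -1.97 (SE 0.0869, limma adjusted p = 6.08e-05), which the pseudocount makes smaller at this level. DESeq2 on recovered reads gave -3.58. Cilp2, a cartilage matrix protein, went from 5.85 ± 0.579 to 0.762 ± 0.161 FPKM (-1.96). Jag2, a Notch ligand, fell from 4.91 ± 0.272 to 0.739 ± 0.00620 FPKM (-1.76). For these low genes too DESeq2 gave larger falls, -2.94 for Cilp2 and -2.75 for Jag2. The cytokine gene Il11 went from 11.7 ± 0.287 to 2.48 ± 0.374 (-1.87) and Wnt9a, a secreted Wnt ligand, from 9.66 ± 0.125 to 2.20 ± 0.602 (-1.76). Rgcc changed by -1.92, Mreg by -1.90, Celf5 by -1.88, Pltp by -1.87 and the potassium channel gene Kcnj4 by -1.81. The Notch receptor genes Notch3 (46.6 ± 2.31 to 16.6 ± 1.09 FPKM, log2 change -1.44) and Notch1 (10.6 ± 0.204 to 5.54 ± 0.130 FPKM, -0.82) fell as well.

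The largest rises among named protein-coding genes were those of Ifi27 (4.39 ± 0.261 to 15.4 ± 2.42 FPKM, log2 change 1.59, limma adjusted p = 0.000252), Ankrd1 (1.24 ± 0.347 to 5.34 ± 0.526, 1.51) and Trim30a (0.347 ± 0.0512 to 2.83 ± 0.394). Ehd2 rose by 1.29, Yif1b by 1.23, the transcription factor gene Klf2 by 1.17, S100a7a by 1.12, the caveolar gene Cavin2 by 1.11, Ifi202b by 1.10 and Ctgf, a secreted matricellular protein, by 1.07 (78.0 ± 2.07 to 165 ± 8.61 FPKM). Trim30a, Ifi202b and S100a7a belong to families of similar genes, so part of their reads could stem from a relative.

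The p53 target genes fell as a group. Of 70 measured members of the 3 target lists, 52 fell, 3 rose and 15 did not pass (54 and 4 adjusted over the list alone), with a median log2 change of -0.40. Camera called the group lower (adjusted p = 1.49e-18; adjusted p = 0.0192 with an estimated correlation). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, went from 382 ± 3.27 to 254 ± 7.16 FPKM (log2 change -0.59, SE 0.0408, limma adjusted p = 0.000252). The gene (ENSMUSG00000023067) lies on mm10 chromosome 17, 29090976 to 29100727, plus strand. Mdm2, the ubiquitin ligase of p53 (ENSMUSG00000020184, chromosome 10, 117688875 to 117710758, minus strand), went from 490 ± 8.58 to 370 ± 18.7 FPKM (-0.40, limma adjusted p = 0.00207). Ccng1 had a log2 change of -0.42 (SE 0.0644, limma adjusted p = 0.00432). The 3 members that rose were Tigar (0.23), Dyrk3 (0.33) and Cgrrf1 (0.28). In place of 3, 1 member rose without shLuc_dox replicate 2 or 3 or without shMettl3_dox replicate 1 or 2. Of the 75 targets fixed beforehand, 51 were in the authors' deposited table of lower genes, which was chosen on these same samples and is no independent evidence.

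In the list of arrest, survival and feedback targets, 24 of 27 measured members fell and 1 rose (25 and 1 adjusted over the list alone; camera adjusted p = 1.18e-14; adjusted p = 0.0192 with an estimated correlation). The cytokine gene Lif went from 34.6 ± 1.75 to 12.4 ± 0.382 FPKM (log2 change -1.41) and Trp53inp1 from 82.5 ± 2.90 to 41.5 ± 2.56 (-0.97). Among repair and metabolism targets 19 of 28 fell and 2 rose (19 and 3 adjusted over the list alone; camera adjusted p = 9.00e-08; adjusted p = 0.0192 with an estimated correlation). Those with the smallest p were Pltp, a phospholipid transfer protein (34.4 ± 0.788 to 8.71 ± 0.492 FPKM), Dcxr (-0.91), Abhd4 (-0.64) and Zfp365 (-0.63). Of the repair and metabolism targets, 0 rose without shLuc_dox replicate 2 or 3 or without shMettl3_dox replicate 1 or 2 (limma; 3 rose at an unadjusted p under 0.05 with all libraries, and 2 by edgeR and by DESeq2).

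Apoptosis targets were lower in part. Of 15 measured, 9 fell and 0 rose (10 and 0 adjusted over the list alone; limma found 0 higher at an unadjusted p under 0.05, as did edgeR and DESeq2 after adjustment). Fas, a death receptor, went from 14.2 ± 1.04 to 6.40 ± 0.546 FPKM (log2 change -1.04). Bbc3, which encodes the BH3-only protein Puma, went from 38.7 ± 1.11 to 24.9 ± 2.57 FPKM (-0.62, limma adjusted p = 0.00185), and Perp, Apaf1 and Pidd1 changed by -0.56, -0.59 and -0.46. Bax stood at 148 ± 8.98 and 153 ± 17.4 FPKM (0.04, SE 0.0892, limma adjusted p = 0.778). Pmaip1, which encodes Noxa, stood at 14.4 ± 0.713 and 15.1 ± 0.536 FPKM (0.06, SE 0.0517, limma adjusted p = 0.407). The list was called lower by camera (adjusted p = 2.94e-05; adjusted p = 0.157 with an estimated correlation).

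**Figure D2:**
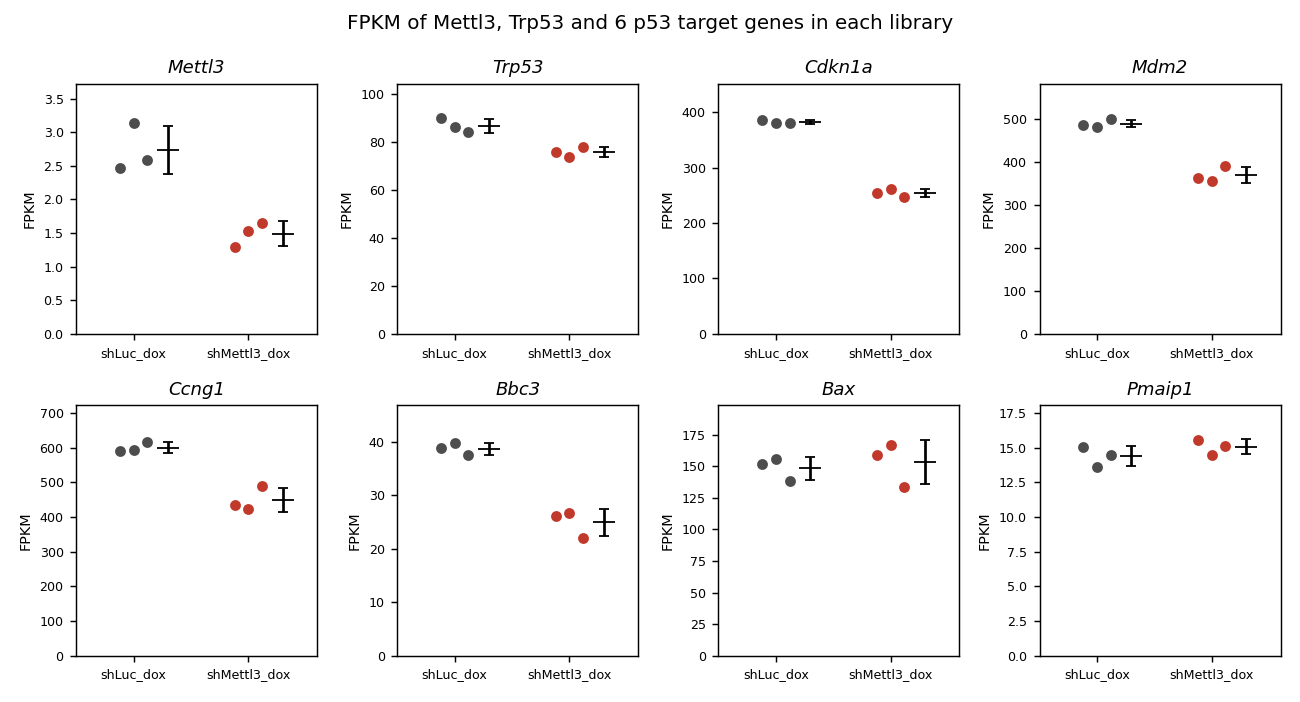
Points are the FPKM of single libraries (vertical axes, from 0), grey for shLuc_dox and red for shMettl3_dox; the bar beside each group is its mean with the SD of 3 libraries. Cdkn1a, Mdm2, Ccng1 and Bbc3 were lower in every shMettl3_dox library than in every shLuc_dox library, while the groups overlap for Bax and Pmaip1.

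Trp53 mRNA (ENSMUSG00000059552, mm10 chromosome 11, 69580359 to 69591873, plus strand) was 86.7 ± 2.88 FPKM in shLuc_dox and 75.8 ± 2.03 FPKM in shMettl3_dox (ratio 0.874, log2 change -0.19, SE 0.0423, limma adjusted p = 0.0167). The list headed p53 and its upstream DNA damage kinases also holds regulators that are not kinases, such as Mdm4, Ep300 and Usp7. Of its 16 members 5 fell and 0 rose (5 and 0 adjusted over the list alone). In limma 2 were higher at an unadjusted p under 0.05, and 2 were higher by edgeR and by DESeq2. The 5 were Trp53, the damage kinase genes Chek2 (-0.39) and Atm (-0.33), the p53 inhibitor gene Mdm4 (-0.35), and Rchy1 (-0.21). The list as a whole was not called (camera adjusted p = 0.359). Trp53 missed the threshold without shLuc_dox replicate 1 or 2 or shMettl3_dox replicate 1 or 2 (adjusted p from 0.0532 to 0.0629), and Atm without shLuc_dox replicate 2 or 3 or shMettl3_dox replicate 1 or 2 (0.0509 to 0.0639). The list count was 3 without shLuc_dox replicate 1 and 2 without shLuc_dox replicate 2, shMettl3_dox replicate 1 or shMettl3_dox replicate 2.

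Among 22 m6A writers, erasers and readers other than Mettl3, 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0584). The writer subunit genes Wtap (14.6 ± 0.531 to 19.5 ± 0.349 FPKM, log2 change 0.40) and Virma (0.28) rose, as did the RNA-binding protein genes Hnrnpc (0.21) and Igf2bp2 (0.23). Mettl14, the partner of Mettl3, was at 5.14 ± 0.320 and 5.74 ± 0.602 FPKM (0.13, limma adjusted p = 0.263). The 7 rises became 4 with the protein-coding scaling and 2 without shLuc_dox replicate 1 or 2 or shMettl3_dox replicate 1, where Hnrnpc and Igf2bp2 lost their calls (limma adjusted p from 0.0518 to 0.0572). The 2 that fell were Mettl5 and Igf2bp1; 0 members fell when any library but shMettl3_dox replicate 3 was left out, and 1 without that one (limma; 2 at an unadjusted p under 0.05 with all libraries, 1 by edgeR and 2 by DESeq2). The camera adjusted p was 0.0341 without shLuc_dox replicate 3 and 0.0420 without shMettl3_dox replicate 2; with all libraries, adjusted p = 0.378 with an estimated correlation.

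Of 30 G2/M and mitosis genes 20 rose and 0 fell (21 and 0 adjusted over the list alone; limma found 0 lower at an unadjusted p under 0.05, as did edgeR and DESeq2 after adjustment). Their median log2 change was 0.23 (camera adjusted p = 4.39e-09; adjusted p = 0.0760 with an estimated correlation). The phosphatase gene Cdc25b went from 9.93 ± 0.109 to 16.6 ± 0.799 FPKM (0.69) and the mitotic transcription factor gene Foxm1 from 18.5 ± 0.347 to 24.1 ± 0.261 (0.36). Birc5 rose by 0.42 and the kinase gene Aurka by 0.36. Of 32 replication and G1/S genes 8 fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.00161; adjusted p = 0.0860 with an estimated correlation). The ribonucleotide reductase gene Rrm2 changed by -0.52 (297 ± 2.86 to 208 ± 9.71 FPKM), E2f1 by -0.46, Slbp by -0.28 and Tk1 by 0.37. The G2/M count was 13 without shLuc_dox replicate 1 and 12 without shMettl3_dox replicate 1. The G1/S count of rises was 1 without shLuc_dox replicate 3, and that of falls was 4 without shLuc_dox replicate 1 or 2 or shMettl3_dox replicate 1, 5 without shMettl3_dox replicate 2 and 15 with array weights.

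Of 35 double-strand break repair genes 4 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.481). Mdc1 went from 18.2 ± 0.690 to 14.8 ± 0.234 FPKM (log2 change -0.28), Rad51d changed by -0.28, Nhej1 by -0.27 and Nbn by 0.39.

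Immediate-early and short-lived mRNAs went both ways, with 11 falls and 9 rises among 31 measured (14 and 10 adjusted over the list alone; camera adjusted p = 0.160). Junb had a log2 change of -1.29 (SE 0.0581), and Zfp36, which encodes an mRNA decay factor, went from 18.8 ± 0.427 to 8.20 ± 0.321 FPKM (-1.10). Atf3 changed by -1.26 and Fos by -0.83, while Klf2 and Ctgf rose. Of 23 RAS-MAPK output genes 5 fell and 3 rose (5 and 4 adjusted over the list alone; camera adjusted p = 0.104). The ligand gene Areg changed by -0.94, the MAPK phosphatase genes Dusp5 and Dusp6 by -0.34 and -0.27, and Emp1 by 0.37. The RAS-MAPK falls numbered 3 without shLuc_dox replicate 2, and the rises 1 without shLuc_dox replicate 3 or shMettl3_dox replicate 1 or 2.

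Inflammatory genes were lower in part. Ptgs2, which encodes cyclooxygenase 2, fell from 17.3 ± 1.82 to 5.28 ± 0.431 FPKM (log2 change -1.54, SE 0.0876, limma adjusted p = 0.000127). Ccl5 changed by -0.61 and Csf1 by 0.31. These were among 6 falls and 1 rise in 13 measured NF-kB and secreted genes (6 and 3 adjusted over the list alone; camera adjusted p = 0.221). In place of 6, 3 fell without shLuc_dox replicate 1 or 2 or shMettl3_dox replicate 2 or 3, and 2 rose without shMettl3_dox replicate 2. Of 19 interferon-stimulated genes 7 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.481). Bst2 went from 30.3 ± 2.84 to 49.4 ± 6.82 FPKM (0.68), whereas Cxcl10 changed by -0.67, Ifi35 by -0.64 and the RNA sensor gene Ifih1 by -0.41. In place of 7, 4 rose without shLuc_dox replicate 1 and 3 without shLuc_dox replicate 2.

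In the endoplasmic reticulum and integrated stress response list 13 of 29 genes rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.0236; adjusted p = 0.133 with an estimated correlation). The rises with the smallest p were in amino acid and serine metabolism genes and their activator: Asns (28.9 ± 2.06 to 46.6 ± 3.46 FPKM, log2 change 0.67), Psat1 (0.47), Shmt2 (0.38) and Atf4 (75.9 ± 3.22 to 102 ± 2.92 FPKM, 0.41). The list missed the threshold without shMettl3_dox replicate 1 (adjusted p = 0.0510), and 3 members fell when any library but shMettl3_dox replicate 3 was left out.

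Of 22 cholesterol synthesis genes 7 fell and 2 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.0511). Insig1, which encodes a sterol-sensing regulator of the pathway, went from 15.1 ± 0.670 to 10.2 ± 0.411 FPKM (log2 change -0.53). Acat2 went from 35.5 ± 2.57 to 27.4 ± 0.717 FPKM (-0.36). In place of 2, 1 rose without any 1 of the shLuc_dox replicates or without shMettl3_dox replicate 2. The camera adjusted p passed the threshold without shLuc_dox replicate 1 (0.0253), shMettl3_dox replicate 2 (0.0475) or shMettl3_dox replicate 3 (0.0398), with quantile normalization (0.0417), with the GC and length trend removed (0.0397) and without the filter on low values (0.0345). With an estimated correlation and all libraries the adjusted p was 0.157. Of 16 matrix and fibroblast genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.255). Tnc, which encodes the matrix protein tenascin C, fell from 89.3 ± 1.99 to 42.3 ± 2.07 FPKM (-1.06), and the receptor gene Pdgfra changed by -0.45, Sparc by 0.33 and Col6a2 by 0.30. Pdgfra missed the threshold without shLuc_dox replicate 1, without shMettl3_dox replicate 2 and without the filter on low values (limma adjusted p = 0.0667, 0.0537 and 0.0635). Col6a2 missed it without shLuc_dox replicate 1, shMettl3_dox replicate 1 or shMettl3_dox replicate 2 (limma adjusted p from 0.0502 to 0.0602). The rises numbered 1 without shLuc_dox replicate 1 or shMettl3_dox replicate 1 and 2 without shLuc_dox replicate 2 or 3, and the falls 1 without shLuc_dox replicate 1 or shMettl3_dox replicate 2.

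Of 35 ribosomal protein genes 8 rose, 0 fell and 27 did not pass (8 and 0 adjusted over the list alone; limma found 0 lower at an unadjusted p under 0.05, as did edgeR and DESeq2 after adjustment). Their median log2 change was 0.10 (camera adjusted p = 0.00336; adjusted p = 0.424 with an estimated correlation; adjusted p = 0.328 after quantile normalization). Rps6 rose by 0.33, Rpl4 by 0.24 and Rpl5 by 0.21. After quantile normalization Rpl4 was at 0.11 (limma adjusted p = 0.142) and Rpl5 at 0.12 (0.275). Without the filter on low values Rps6, Rpl4 and Rpl5 missed the threshold (limma adjusted p = 0.0659, 0.221 and 0.0596), as did Rps6 with the GC and length trend removed (0.0593) and Rpl5 with the protein-coding scaling (0.0533). Rpl4 and Rpl5 also missed it without shLuc_dox replicate 1 or 2, and Rpl5 without shMettl3_dox replicate 1 (limma adjusted p from 0.0578 to 0.0772). The count was 2, 1, 2 and 5 without shLuc_dox replicate 1, shLuc_dox replicate 2, shMettl3_dox replicate 1 and shMettl3_dox replicate 2, and 21 without shMettl3_dox replicate 3, the library that stood apart. These genes have many processed copies in the genome, so their reads are less certain.

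Of the 13 mitochondrially encoded mRNAs 0 passed in limma in either direction (1 higher at an unadjusted p under 0.05; 2 higher by edgeR and 1 by DESeq2). Camera did not call the list (adjusted p = 0.145), but did without shLuc_dox replicate 3 (0.0317) or shMettl3_dox replicate 1 (0.0320); with all libraries, adjusted p = 0.621 with an estimated correlation. In limma, 1 member was higher without shMettl3_dox replicate 1 or 2, and 1 was lower without shMettl3_dox replicate 3. mt-Nd5 had a log2 change of 0.36 (limma adjusted p = 0.0587), mt-Nd6 of 0.31, mt-Nd4 of 0.17 and mt-Atp6 of 0.15. mt-Nd5 was called higher by edgeR (adjusted p = 0.00423) and DESeq2 (adjusted p = 0.0340), without shMettl3_dox replicate 2 (limma adjusted p = 0.00963), and with array weights, a minimum mean of 5 FPKM or protein-coding genes alone (limma adjusted p from 0.0222 to 0.0398). mt-Nd6 was called higher by edgeR (adjusted p = 0.0204) and with array weights (limma adjusted p = 0.0326), and mt-Atp6 without shMettl3_dox replicate 1 (limma adjusted p = 0.0383). Mitochondrial reads were 1.76 ± 0.158% of recovered reads in shLuc_dox and 2.00 ± 0.305% in shMettl3_dox, with the highest share, 2.34%, in shMettl3_dox replicate 3.

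Most markers of other cell types had a mean under 1 FPKM and were not tested: 12 of 14 leukocyte, 10 of 14 epithelial, 10 of 12 endothelial and 11 of 14 muscle, neural and germ markers. Among these were Ptprc (0.00289 and 0.00271 FPKM in shLuc_dox and shMettl3_dox), Cdh1 (0.0425 and 0.00706) and Krt8 (0.124 and 0.0639). Both tested leukocyte markers, Cd68 (16.8 ± 1.40 to 10.1 ± 0.838 FPKM) and Cd14, were lower. So were all 4 epithelial markers measured, Krt18 (46.2 ± 1.66 to 29.1 ± 3.93 FPKM), Esrp2, Krt19 and Epcam, as well as the endothelial marker Flt1 (4.34 ± 0.167 to 2.52 ± 0.115) and the muscle marker Des (6.28 ± 0.461 to 2.80 ± 0.436). Nes, at 52.7 ± 2.00 and 47.7 ± 5.12 FPKM, and Map2 did not pass, with log2 changes of -0.15 and 0.09. Eng did not pass in limma (log2 change 0.36, adjusted p = 0.0664) but was called higher by edgeR (0.67, adjusted p = 0.0177) and DESeq2 (0.66, adjusted p = 0.0166). It also passed in limma with quantile normalization, without the eBayes trend, with array weights and among protein-coding genes alone (adjusted p from 0.0188 to 0.0378). Cd14 missed the threshold without shLuc_dox replicate 1 or 2 or shMettl3_dox replicate 2 or 3 (limma adjusted p from 0.0525 to 0.0783). Epcam missed it without shLuc_dox replicate 1 or 2 (limma adjusted p = 0.0635 and 0.0610). Without the filter on low values Cd14 and Epcam missed it as well (limma adjusted p = 0.0695 and 0.0584).

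**Figure D3:**
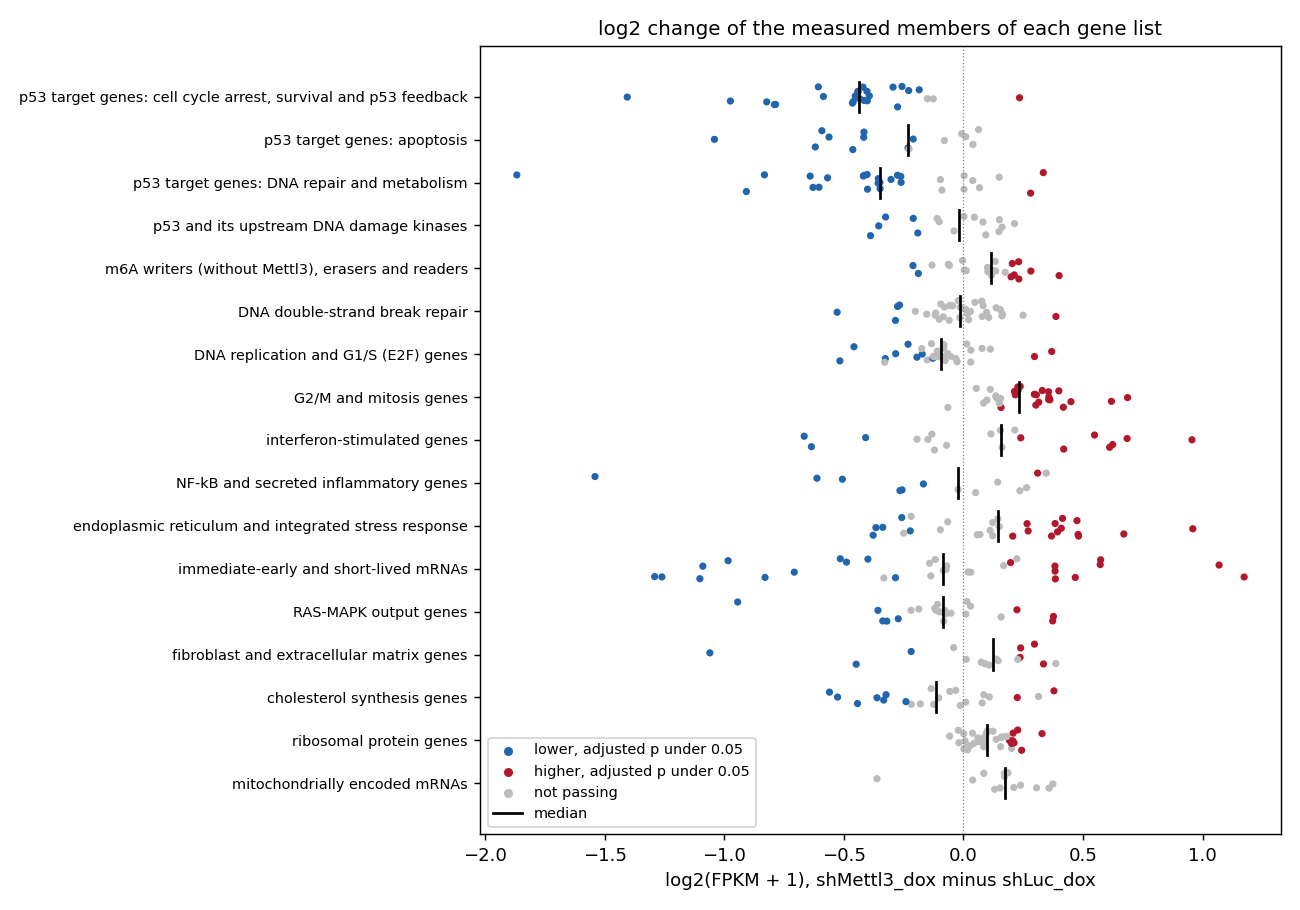
Each point is a measured member of a gene list (rows), placed by its difference in log2(FPKM + 1), shMettl3_dox minus shLuc_dox; blue and red members passed as lower and higher, grey ones did not pass, and black bars are medians. The medians of the 3 p53 target lists are -0.44, -0.23 and -0.35, with 59 of the 70 members below 0, and that of the G2/M list is 0.23, with 1 of 30 members below 0.

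The authors' deposited table lists 1960 genes as lower, chosen on these same libraries. Of these, 1670 were tested here, all 1670 were lower by sign and 1480 (88.6%) passed as lower. Across the genes shared, the log2 changes had a Pearson r of 0.929 and a Spearman rho of 0.965, where genes are not independent replicates. The smallest adjusted p-values in the authors' deposited table belong to Notch3 (log2 fold change -1.48), Nptx1 (-1.46), Col2a1 (-3.56), Pltp (-1.98) and Tnc (-1.07). For Col2a1, DESeq2 on recovered reads gave -3.58, against -1.97 in log2(FPKM + 1). Nptx1, which encodes a neuronal pentraxin, went from 35.3 ± 0.419 to 12.7 ± 0.305 FPKM (log2 change -1.40). DESeq2 on the recovered reads of all genes called 1963 lower, 1939 of them in the authors' deposited table, and 2030 higher.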

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

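Removing the GC and length trend and testing protein-coding genes alone were chosen after seeing the data; the other alternatives were planned. With a minimum fold of 1.5, 352 genes were lower and 126 higher in limma, and 317 of the authors' listed genes passed. At that fold 16 p53 targets were lower and 0 higher, and 33 list members were lower and 10 higher. These smaller counts follow from the stricter criterion. Without a minimum fold, 4 p53 targets were higher in limma at an unadjusted p under 0.05, and 3 by edgeR. Mettl3, at -0.58 on the log2(FPKM + 1) scale, missed the minimum fold because of the pseudocount (-0.83 and -0.87 with pseudocounts of 0.1 and 0.01). Without the filter on low values 53 list members and 1 p53 target were higher and 6 lists were called higher. Among them were the m6A, interferon and matrix lists (camera adjusted p = 0.00376, 0.0345 and 0.0324). With the filter, camera gave these lists adjusted p = 0.0584, 0.481 and 0.255 at the same preset correlation. An estimated correlation with the filter gave 0.378, 0.574 and 0.424. In the same setting 7 lists were called lower, in place of 5, with the epithelial marker and cholesterol lists added (camera adjusted p = 0.0241 and 0.0345). With the filter, camera gave the cholesterol list adjusted p = 0.0511, and 0.157 with an estimated correlation. The epithelial list then had 4 tested members, too few for camera. The cause of the added calls was not tested. Camera called 5 lists lower and 3 higher, and 3 and 0 with an estimated correlation; fry, which does not compare a list with other genes, called 9 lower. With any 1 library left out, 1060 to 1646 genes were lower and 1013 to 1854 higher, 47 to 91 list members and 1 to 4 p53 targets were higher, and 3 to 5 lists were called higher, with fewer samples in each fit. Quantile, median-of-ratios and protein-coding scaling moved the median of all genes by less than 0.1. edgeR called 1976 lower and 2047 higher, and 95.3% of the main calls were called in the same direction. The replicate numbers did not pair the samples (correlations of 0.0340, -0.00680 and 0.0631 for equal numbers). With the number as a block, 1525 genes were lower and 1676 higher, and mt-Nd5 passed in limma (adjusted p = 0.0372). The cholesterol and mitochondrial lists passed in camera with the block (adjusted p = 0.0398 and 0.0353). Without it, camera with an estimated correlation called neither (adjusted p = 0.157 and 0.621). Of 94 named genes called besides Mettl3, 47 kept direction and call under every alternative in which they were tested, and 0 reversed. The minimum fold alone removed 47. In the self-test limma recovered 14% of genes changed 1.2-fold. Only 50 genes were changed at each fold there, against 3396 that passed here, so the adjustment was stricter in the self-test. The 14% is therefore no measure of how many small changes were missed in the data. A minimum mean of 5 FPKM leaves Mettl3 untested, as it does other low named genes such as Col2a1, Cilp2 and Jag2.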

Other observations

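The scan of symbol families, the removal of the GC and length trend, and the tests of a shared direction and of a single size among p53 targets were chosen after results had been seen. Among 63 families of genes that share a symbol stem and have at least 15 tested members, the mitochondrial large-subunit family Mrpl had 19 of 48 members higher (camera adjusted p = 0.000118) and the small-subunit family Mrps 11 of 29 (adjusted p = 0.00545); neither call held with an estimated correlation (adjusted p = 0.675 for each). Mrpl43 went from 41.2 ± 0.338 to 60.9 ± 1.29 FPKM (log2 change 0.55) and Mrpl50 had a log2 change of 0.48 (SE 0.0515), both named after their values were seen for the smallest p. The Rpl stem, that of cytosolic large-subunit genes, had 11 of 78 members higher (camera adjusted p = 0.00875, and 0.848 with an estimated correlation). That share is no larger than the 1763 higher among all 12098 genes tested. Families were formed by stem alone, with no filter on gene type, so a stem can take in pseudogenes and genes of other function. Camera also called higher the stems Eif (12 of 54 higher and 1 lower, adjusted p = 0.0251) and Ube (12 of 38 higher and 2 lower, adjusted p = 0.0258). It called the Map stem lower (14 of 40 lower and 4 higher, adjusted p = 0.0335). Each of the stems Eif, Ube and Map had adjusted p = 0.675 with an estimated correlation.

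After removal of a GC and length trend 54 p53 targets passed as lower, against 52 before, which argues against that trend as the whole cause of the p53 pattern. Without shMettl3_dox replicate 3 the median log2 change of the targets was -0.37 against -0.40. With 52 targets already passing over all libraries, this outcome could be foreseen and decides little. The p53 targets summed to 3808.5 FPKM in that library and to 3830.2 and 3846.8 in shMettl3_dox replicates 1 and 2. A share of 0.843 of the 70 targets had a log2 change below 0, which a lower Trp53 level could give, but with 52 of them already known to be lower this test could hardly have come out otherwise. The targets did not fall by a single size (heterogeneity Q per degree of freedom 25.2 in DESeq2 on recovered reads); this test was added when the folds were known, the share test was expected to be met and this outcome could be foreseen. Knockdown of Mettl3 may underlie the pattern, as a hypothesis. An effect of the hairpin on other transcripts stays open, since no second hairpin against Mettl3 is labelled. A difference between cultures stays open as well, since the labels do not say that replicates came from separate cultures.

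Mitochondrial ribosomal protein genes, a pattern noticed in these data, had 30 of 77 members higher and 0 lower (limma; 0 lower at an unadjusted p under 0.05, and 0 by edgeR and DESeq2). After removal of the GC and length trend 26 were higher and 1 lower, and without shMettl3_dox replicate 3 the median log2 change was 0.21 against 0.17, which argues against either as the whole cause. The count of higher members was 20, 20 and 18 without shLuc_dox replicates 1, 2 and 3 and 18 without shMettl3_dox replicate 1. With all libraries it was 22 with the protein-coding scaling (median log2 change 0.14), 27 with quantile normalization (0.17) and 28 with median-of-ratios scaling (0.16). A response to the knockdown may be involved, which remains a hypothesis, since the family calls did not hold with an estimated correlation.

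m6A is deposited away from exon junctions, so loss of the mark could raise mRNAs with few junctions. The values met only part of the conditions set beforehand, so they did not bear this out. They cannot exclude it either, since Mettl3 mRNA was only partly lowered (ratio 0.545). Across 10650 protein-coding genes the partial Spearman rho between junctions per kilobase and the log2 change was -0.0650, which met the condition on size. The other condition was a value lower than in every other split of the 6 libraries. Another split reached -0.107 when taken in either direction, so the value does not stand out. Each other split mixes both groups, so this comparison is no measure of chance. The plain rho was -0.0219, and 2.12 times as large with length and GC content partialled out; with no value that stands out, this ratio decides nothing about GC content or length. The 2663 genes with the fewest junctions per kilobase and the 2663 with the most had median log2 changes of 0.02 and 0.02.

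Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 3396 genes past the threshold; the highest of the others gave 0 in limma, the tool used for the splits (159 to 575 genes at an unadjusted p under 0.05, against 4853). Each other split holds libraries of both groups on each side, so the difference between the groups adds to its spread and few calls are likely. Its count is therefore no measure of chance. So few splits also cannot give a share under 0.05.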
